A study of Mus musculus with 2 samples.

How the data were processed

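RNA from estradiol-treated G1E-ER4 cells was measured in 2 libraries of 1 group, which the labels number as biological replicates 1 and 2. For each library a table of genes and a table of transcripts were used. Per the text that accompanies the deposited tables, reads were aligned to the mouse assembly mm10 and quantified on GENCODE annotation M4 from transcriptome alignments. The aligner, the quantifier and their versions are not given in the sources used here. Replicates were not pooled by the authors.

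The deposited expected counts are estimated numbers of fragments per gene or transcript, not normalised, and need not be whole because a fragment that matches several transcripts is divided between them, per the file headers and the values. The deposited TPM values are transcript abundances scaled to transcript length, with the same sum over all transcripts in each library. The deposited FPKM values are fragments scaled to effective length and library size, per the file headers. The deposited transcript tables give for each transcript the percent of its gene's TPM. Posterior mean versions of counts, TPM and percent, also made by the authors, served as alternatives. The tables list 43346 mouse genes, of which 42462 matched a symbol by identifier. They also list 97 spike-in sequences, which had no count, and 26248 entries named by number, with 1 count in replicate 1 and 0 in replicate 2, which were left out. Coordinates, biotypes, transcript names and sequences came from GENCODE M21 on GRCm38, the assembly that mm10 names. M4 was not used here, so boundaries of gene models may differ from those used for counting.

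Depth was 31126957 expected counts in replicate 1 and 57853617 in replicate 2. A count of 0 allows up to 3 counts, and intervals and such limits cover counting error only. Genes were called detected at 1 TPM. Levels are given as mean ± SD of the 2 TPM values. Gene pairs were compared by log2 ratios of TPM with the same pseudocount as below. Replicates were compared by Pearson and Spearman correlation across genes with a mean of at least 1 TPM, on log2 values with a pseudocount of 1, with 1000 bootstrap resamples of genes. A log2 ratio on that scale understates differences of genes with low values.

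Expected counts were rounded to whole numbers for count tests. With 1 library on each side, edgeR's quasi-likelihood test has no residual degrees of freedom. Each gene with a summed count of at least 20 was instead tested by a two-sided exact conditional binomial test on library sizes scaled by TMM factors (edgeR 4.0.16), with Benjamini-Hochberg adjustment at 0.05. This test compares libraries, not conditions, and measures counting noise only. "Scaled counts" are counts divided by these library sizes, with a prior count of 2 in ratios. The biological coefficient of variation is the square root of edgeR's common dispersion with an intercept-only design, after edgeR's own filter on low counts. The count test was tested on simulated data in which counts of the real genes were drawn with Poisson noise. Over 10668 genes, it recovered 83.0% of 100 genes changed 1.5-fold and 98.0% of 100 changed 4-fold, and 6.70% of its calls were false.

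Before the data were examined, 28 gene lists, 10 gene pairs, the tests and the rule for named genes were fixed. The lists were core regulators, globins, heme synthesis and iron, erythroid membrane, genes induced by GATA1, genes repressed by GATA1, megakaryocyte, mast cell and basophil, granulocyte and monocyte, lymphocyte, stem and progenitor, pluripotency, fibroblast and stroma, G1/S, G2/M, cell cycle inhibitors, immediate early, heat shock, hypoxia and glycolysis, stress and unfolded protein response, interferon response, cytokine signalling feedback, estrogen receptors and targets, mitochondrially encoded, nuclear oxidative phosphorylation, ribosomal proteins, histones and RNAs without a poly(A) tail, and Y chromosome with Xist. Of the 11 globin and 18 induced symbols, 9 and 16 were analysed here. Named were members of the core regulator, globin and heme lists, the 3 highest and the lowest member of each other list, the 15 genes with the highest mean TPM, the 10 genes with the largest log2 ratio in each direction among those beyond counting noise with a summed count of at least 100, both members of each pair, and the most abundant transcript of core regulators. Genes named beyond this rule are said to have been chosen after their values were seen.

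The 8 contrasts between lists used two-sided permutation tests of the difference in mean log2(TPM + 1), with 100000 resamples of genes between lists. List levels were placed among 10000 random lists of the same size drawn from genes with TPM above 0. List differences between replicates, for lists with at least 5 tested members, were placed among 10000 random lists drawn member by member from the 200 genes nearest in mean expression, and a list stood apart outside the 2.5 to 97.5 percentiles. Sequence shared between genes was searched with 31-base words of annotated transcripts, 1 in 4 of which was sampled. A gene counted as sharing with another if at least 5 sampled words and 10% of its words occurred in it, and overlapping genes were not counted.

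Alternatives were a pseudocount of 0.1, other detection levels, FPKM, DESeq2 1.42.0 size factors, total counts, posterior mean values, filters on low values and each replicate left out. Software was R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.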

Results

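Polyadenylated RNA was sequenced in paired ends from G1E-ER4 cells after 3 h in 10 nM 17beta-estradiol. G1E-ER4 is an immortalised mouse erythroid progenitor line in which the endogenous Gata1 gene is disrupted and the transcription factor GATA1 is supplied as a fusion to the ligand-binding domain of the estrogen receptor, so that estradiol switches the factor on. The labels describe 1 group of 2 biological replicates and give both the same cell sample record, so the spread between them may be technical. No untreated library was analysed here, and the values below are levels after estradiol, not responses to it. Replicate 1 held 31126957 expected counts and replicate 2 held 57853617. A level of at least 1 TPM, a unit of transcript abundance scaled to transcript length and to the same total in each library, was reached by 8777 genes in both libraries, of which 8281 were protein-coding. A further 439 genes reached that level only in replicate 1 and 328 only in replicate 2, and 27574 genes had no count in either.

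The regulators of the erythroid program were among the more abundant transcripts. All 25 members of the core regulator list exceeded 1 TPM in both libraries, 10 exceeded 100 TPM in both, and the median of the list lay above those of all 10000 random lists of that size. Zfpm1 (chromosome 8, 122282141 to 122337251, plus strand), which encodes the GATA1 cofactor FOG1, led the list at 1933 TPM ± 699 (SD, n = 2). Of the partners of GATA1 in its DNA-bound complex, Lmo2 stood at 974 TPM ± 449, Tcf3 at 664 TPM ± 141, Ldb1 at 439.7 TPM ± 63.3 and Tal1 at 99.4 TPM ± 28.6 (SD, n = 2). Klf1 (chromosome 8, 84901928 to 84905291), an activator of adult beta globin, stood at 568 TPM ± 308, and the repressor Gfi1b at 278 TPM ± 130.4. Progenitor regulators were also measurable: Myc at 396 TPM ± 101.0, Gata2 (chromosome 6, 88193891 to 88207032) at 323 TPM ± 72.8, Runx1 at 312 TPM ± 77.4, Myb at 53.5 TPM ± 22.9 and Spi1 at 37.0 TPM ± 16.4 (SD, n = 2).

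Among the remaining members, Bcl11a and Zbtb7a, both repressors of embryonic or fetal globin genes, reached 88.7 TPM ± 12.5 and 85.3 TPM ± 39.3. Nfe2 stood at 69.0 TPM ± 32.7, Cbfa2t3 at 33.7 TPM ± 9.28, Lyl1 at 32.0 TPM ± 1.57 and Fli1 at 15.1 TPM ± 2.35. The erythropoietin receptor gene Epor was close in both libraries at 53.2 TPM ± 2.35, whereas its signalling kinase Jak2 stood at 15.5 TPM ± 9.82 (SD, n = 2). The signal transducers Stat5b and Stat5a reached 66.0 TPM ± 11.3 and 23.6 TPM ± 7.73, and the survival gene Bcl2l1 reached 39.0 TPM ± 8.54.

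**Figure D1:**
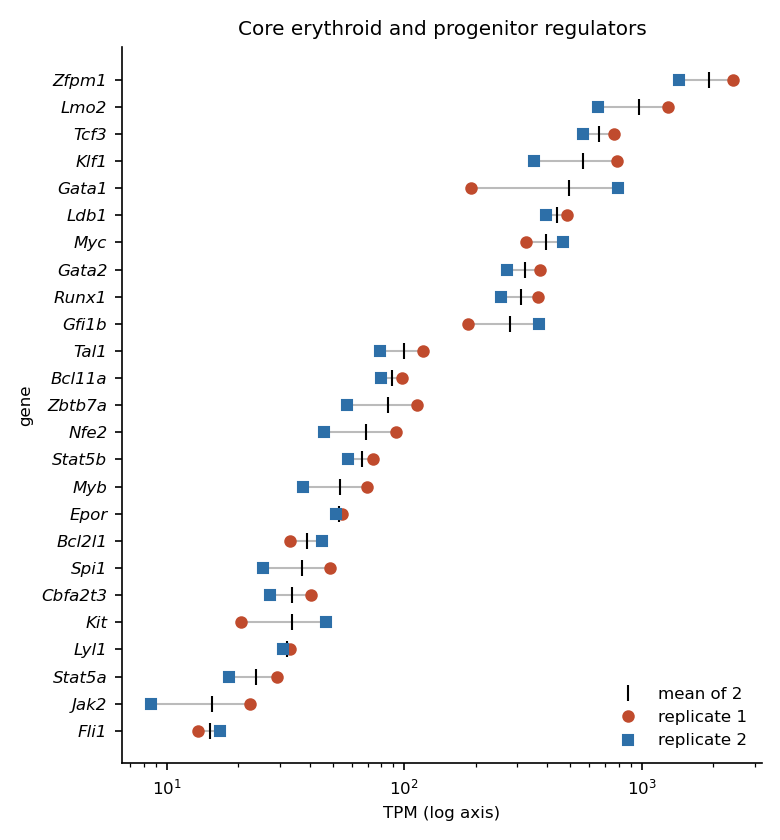
TPM of the 25 core regulators on a log axis, with circles for replicate 1, squares for replicate 2 and a tick for their mean. Zfpm1 was highest at 1933 TPM, Fli1 was lowest at 15.1 TPM, and Gata1 had the widest gap between the libraries, 190.3 against 799 TPM.

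Gata1 itself (chromosome X, 7959260 to 7978071, minus strand) was the regulator on which the libraries differed most. It reached 190.3 TPM in replicate 1 and 799 TPM in replicate 2, a 5.33-fold difference in scaled counts in favour of replicate 2. Reads from the introduced fusion and from the disrupted locus are not separated in these tables. Kit, the receptor for stem cell factor, was 3.14-fold and Gfi1b 2.53-fold higher in replicate 2, and Jak2 was 2.05-fold higher in replicate 1. Of the 25 regulators, 10 were lower and 13 higher in replicate 1 beyond counting noise, with identical numbers when adjusted over the list alone. The median log2 ratio of 0.10 lay inside the range of matched random lists.

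Adult globin transcripts were abundant in both libraries and differed several-fold between them, while embryonic globin transcripts were all but absent. The near-identical alpha globin genes Hba-a1 (chromosome 11, 32283511 to 32284465) and Hba-a2 (chromosome 11, 32296489 to 32297298) summed to 1713 TPM in replicate 1 and 9280.4 TPM in replicate 2, a 6.01-fold difference in scaled counts. Their separate values are uncertain because the genes share reads. Adult beta globin Hbb-bs (chromosome 7, 103826534 to 103828096) and its neighbour Hbb-bt summed to 874 TPM in replicate 1 and 9571 TPM in replicate 2. That is a 13.0-fold difference in scaled counts. Separately, Hbb-bs stood at 863 and 9484 TPM and Hbb-bt at 11.2 and 87.2 TPM. Their counts were not whole either, so this division is also uncertain. No count fell on Hbb-y, Hba-x, Hbb-bh0 or Hbb-bh2, and 1 count in each library fell on Hbb-bh1. The annotation classes Hbb-bh0 as an unprocessed pseudogene. A count of 0 allows up to 3 counts, 9.64e-06% of replicate 1 and 5.19e-06% of replicate 2. With 9 members analysed here, 5 of them under 0.1 TPM in both libraries, the globin list had a median at the 3.10 percentile of random lists.

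All 21 genes of heme synthesis and iron handling exceeded 1 TPM in both libraries. The ferritin chains dominated, with Fth1 (chromosome 19, 9980598 to 9985098) at 15600 TPM ± 1798 and Ftl1 at 8683 TPM ± 46.2 (SD, n = 2). Along the heme pathway the levels were uneven. The erythroid first enzyme Alas2 reached 4.26 TPM ± 3.45 and its ubiquitous counterpart Alas1 reached 2.97 TPM ± 2.42, below Alad at 273 TPM ± 223, Cpox at 255 TPM ± 71.0 and Fech at 155 TPM ± 26.3. Ppox stood at 50.1 TPM ± 16.7, Urod at 43.1 TPM ± 43.7 and Uros at 1.99 TPM ± 0.728. Of the other members, Slc25a38 reached 123 TPM ± 60.2, Steap3 99.4 TPM ± 4.53, Abcb10 70.2 TPM ± 25.4, the transferrin receptor gene Tfrc 53.6 TPM ± 46.6 and the mitochondrial iron importer gene Slc25a37 31.4 TPM ± 16.9. Aco1, Slc11a2, Slc40a1, Ireb2 and Hmox1 lay between 19.7 and 2.39 TPM. In this list 12 genes were lower and 6 higher in replicate 1 beyond counting noise, also when adjusted over the list alone. Alad was 4.68-fold and Urod 3.77-fold higher in replicate 2.

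Listed markers of other lineages were far less abundant than those of the erythroid membrane. Over 18 genes of the red cell membrane and its skeleton, led by the spectrin gene Sptb at 184 TPM ± 17.6, the ankyrin gene Ank1 at 107 TPM ± 9.72 and Epb41 at 51.1 TPM ± 13.7 (SD, n = 2), the mean log2(TPM + 1) was 3.33. It exceeded the mean of 16 granulocyte and monocyte genes by 3.21 ± 0.27, of 15 lymphocyte genes by 3.21 ± 0.13, of 14 stem and progenitor genes by 3.05 ± 0.06, of 12 pluripotency genes by 3.30 ± 0.18 and of 12 fibroblast and stroma genes by 3.27 ± 0.15 (log2 units, SD between the 2 libraries). For each of these 5 lists the two-sided permutation p over genes was 2e-05, the smallest that 100000 resamples can give, with a Benjamini-Hochberg adjusted p of 3.2e-05 over 8 contrasts. The differences from 14 mast cell and basophil genes (2.88 ± 0.16, permutation p = 0.00014, adjusted p = 0.000187) and from 15 megakaryocyte genes (2.10 ± 0.10, permutation p = 0.0123, adjusted p = 0.0141) were smaller. Genes are not independent replicates, so these p-values describe the lists in these libraries. The median of the erythroid membrane list lay at the 78.8 percentile of random lists and the 54.2 percentile of random protein-coding lists. The differences therefore rest on low levels of the other lists more than on a high level of this one. With members under 0.1 TPM left out, the contrasts with the megakaryocyte, mast cell, lymphocyte and stem lists no longer passed (adjusted p = 0.382 and, for the other 3, 0.160).

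**Figure D2:**
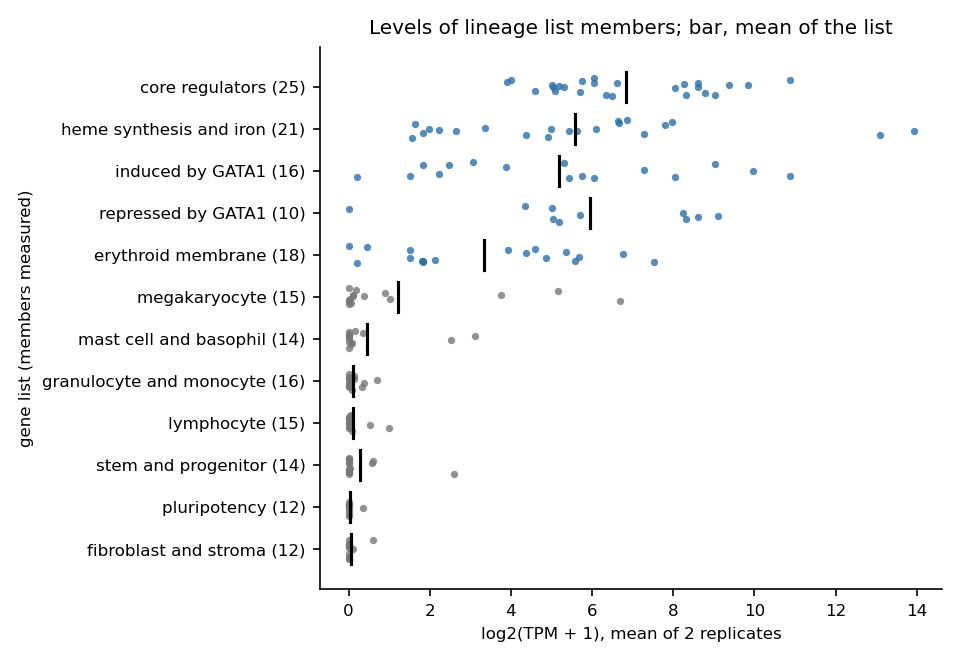
Level of each list member as log2(TPM + 1), averaged over the 2 replicates, with 1 point per gene, a vertical bar at the mean of the list and the number of members in brackets. The erythroid membrane mean was 3.33, and the means of the 7 lists of other lineages ran from 0.03 for pluripotency to 1.23 for megakaryocyte.

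A few single markers of other lineages stood out from their lists. Platelet glycoprotein genes were measurable, with Gp5 at 109 TPM ± 55.1, Gp1ba at 43.0 TPM ± 36.2 and the integrin gene Itga2b at 12.6 TPM ± 1.44, while 7 of the 15 megakaryocyte genes lay under 0.1 TPM in both libraries and Clec1b had no count. Il1rl1 and Hdc, used as mast cell and basophil markers, reached 7.99 TPM ± 2.96 and 4.93 TPM ± 1.95, against 0.28 TPM ± 0.08 for Cpa3 and no count for Mcpt4. Meis1 reached 5.38 TPM ± 2.79, whereas Procr and Erg stood at 0.535 and 0.530 TPM and Ly6a had no count. Spi1 (37.0 TPM), Gata2, Runx1, Myb, Kit and Fli1 were counted as core regulators and are in none of the lists of other lineages. The low levels of those lists depend in part on that choice. In the granulocyte and monocyte, lymphocyte, pluripotency, and fibroblast and stroma lists no member reached 1 TPM in both libraries. The highest of each list were Prtn3 (0.770 TPM), Lck (1.21 TPM), Lefty1 (0.275 TPM) and Col1a2 (0.515 TPM), and no count fell on Lyz2, Cd8a, Nanog, Sox2 or Cxcl12.

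Genes that GATA1 is known to induce were not more abundant than genes it is known to repress. The mean log2(TPM + 1) was 5.18 over 16 induced genes and 5.96 over 10 repressed genes, a difference of -0.78 ± 0.48 (SD between the 2 libraries, permutation p = 0.531, adjusted p = 0.531). The lists hold different genes, whose levels may differ without GATA1, and no untreated library was analysed here. This comparison therefore cannot show whether GATA1 changed either list. Both lists lay high among random lists, at the 99.8 and 99.2 percentiles. Zfpm1, Klf1 and Hba-a1 led the induced list, in which Epb42 was lowest at 0.16 TPM. Hhex at 562 TPM ± 178, Myc and Gata2 led the repressed list, in which Cd34 was lowest at 0.015 TPM.

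Of 10 gene pairs fixed before the data were examined, the first-named member was the higher in both libraries in 9. Klf1 exceeded Spi1 by a log2 ratio of 3.86 ± 0.18, Bcl2l1 exceeded Bcl2 by 3.13 ± 0.77, Nfe2 exceeded Bach1 by 1.69 ± 0.60 and Tal1 exceeded Lyl1 by 1.57 ± 0.35 (SD, n = 2). Epor exceeded Kit by 0.76 ± 0.88 and Alas2 exceeded Alas1 by 0.38 ± 0.08. In replicate 1 the intervals of Alas2 (1.248 to 2.86 TPM) and Alas1 (1.172 to 2.085 TPM) overlapped. Hbb-bs, Hba-a1 and Zfpm1 were set against Hbb-y, Hba-x and Zfpm2, which had no count, so no ratio is given. The pair of GATA factors was the exception, since the log2 ratio of Gata1 to Gata2 was -0.97 in replicate 1 and 1.56 in replicate 2. In expected counts, which are not divided by transcript length, the mean ratios for Alas2, Epor and Nfe2 also turned negative. An exact permutation test of 2 values against 2 cannot give a p below 0.33.

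Genes of translation and energy metabolism had the highest medians of the lists, and genes of cell division also lay high among random lists. Of the 28 gene lists, 13 had medians at or above the 95th percentile of random lists and 11 at or below the 5th. Random lists held no gene at 0 TPM in both libraries, whereas the low lists kept such members, so their low places follow in part from that choice. No count fell on 4 of 15 megakaryocyte genes (1.60 percentile), 7 of 14 mast cell and basophil genes, 7 of 16 granulocyte and monocyte genes, 6 of 15 lymphocyte genes, 6 of 14 stem and progenitor genes, 10 of 12 pluripotency genes and 7 of 12 fibroblast and stroma genes. Ribosomal protein genes (median 2109 TPM ± 2112), mitochondrially encoded genes (366 TPM ± 204), nuclear genes of oxidative phosphorylation (229 TPM ± 135) and heat shock genes (208 TPM ± 29.6) all lay above every random list. The list of replication-dependent histones and RNAs without a poly(A) tail had a median of 72.5 TPM ± 45.6, the G1/S genes 73.0 TPM ± 6.44 and the G2/M genes 49.8 TPM ± 30.0 (SD of the 2 library medians). All 14 genes of that histone and RNA list reached 1 TPM in both libraries, although polyadenylated RNA was sequenced. How much RNA without a poly(A) tail each library carried was not tested. Slbp (334 TPM), Rrm2 (300.2 TPM) and Mcm2 (285 TPM) led the G1/S list, and Ccna2 (856 TPM), Ube2c (424 TPM) and Cdc20 (422 TPM) led the G2/M list. Genes of hypoxia and glycolysis lay at the 99.2 percentile and genes of the integrated stress and unfolded protein response at the 98.7 percentile, with Hspa5 (154 TPM), Ppp1r15a (76.4 TPM) and Atf4 (74.7 TPM) highest.

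Between those limits lay the erythroid membrane (78.8 percentile), cell cycle inhibitors (91.1), immediate early genes (66.2) and cytokine signalling feedback (87.8). Among random lists of protein-coding genes these places were 54.2, 81.8, 43.9 and 76.6. From replicate 1 alone, the inhibitors (95.6) and the feedback genes (96.2) passed the 95th percentile. Trp53 (165 TPM) and Cdkn2c (155 TPM) led the inhibitors, in which Cdkn2b had no count. Junb (59.7 TPM), Ier2 (37.9 TPM) and Egr1 (32.2 TPM) led the immediate early genes, and Mcl1 (546 TPM), Socs2 (114 TPM) and Cish (69.5 TPM) the feedback genes. Interferon response genes (0.26 percentile) and estrogen receptors and their targets (0.06 percentile) were low. Of the latter, Xbp1 (57.9 TPM), Ctsd (45.4 TPM) and Nrip1 (12.9 TPM) were expressed, and Pgr had no count.

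The 15 most abundant genes held 19.98% of TPM in replicate 1 and 21.3% in replicate 2. They comprised the ribosomal protein genes Rplp1, Rpl18, Rpl27a, Rpl28 and Rpl41, the histone genes Hist1h2ap and Hist1h2ad, the ferritin genes Fth1 and Ftl1, Gapdh, Ptma, Ran and Pfn1, and Gm26917 and Gm42418. The annotation classes Gm26917 and Gm42418 as long noncoding RNA genes, and the kind of RNA their reads come from was not tested. The last pair (chromosome 17, 39843013 to 39848788) took 6.83% of all counts in replicate 1 and 4.39% in replicate 2.

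The libraries were not interchangeable. Gapdh (chromosome 6, 125161715 to 125166467, minus strand), the glycolytic enzyme gene often used as a loading control, stood at 956 TPM in replicate 1 and 21738 TPM in replicate 2, a 16.9-fold difference in scaled counts. Rpl41 was 17.1-fold, Rpl28 8.95-fold, Rplp1 3.37-fold and the thymosin gene Ptma 2.94-fold higher in replicate 2, while Hist1h2ad was 4.69-fold and Rpl27a 1.65-fold higher in replicate 1. Across 9269 genes with a mean of at least 1 TPM, Pearson's r of log2(TPM + 1) was 0.887 (bootstrap interval over genes 0.880 to 0.893) and Spearman's rho was 0.882. Genes are not independent replicates, and these values describe this pair of libraries. The chi-square statistic of the counts was 679 per degree of freedom (10634 degrees of freedom), so the libraries differ by far more than sampling noise and were kept as 2 samples. The biological coefficient of variation was 0.470 over 10233 genes.

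**Figure D3:**
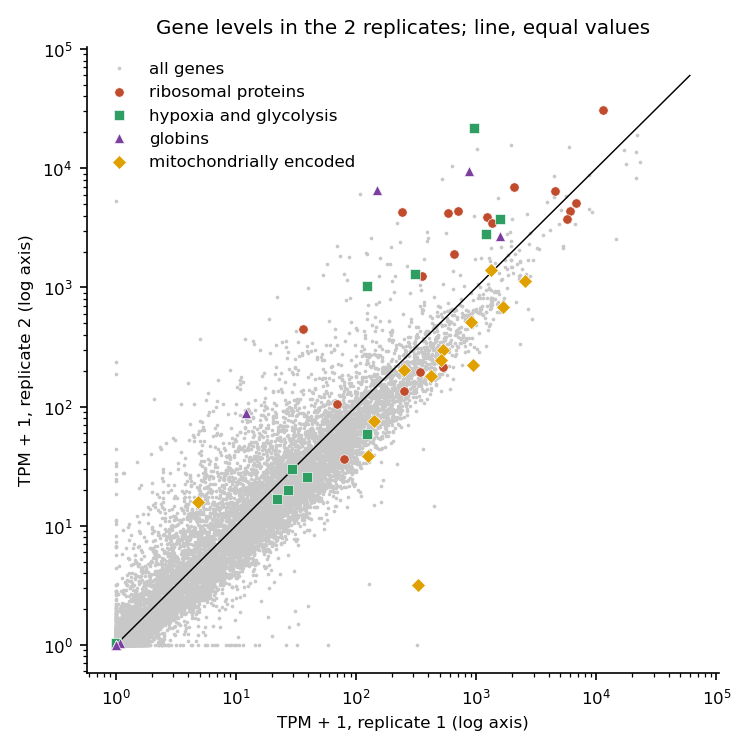
TPM + 1 of every gene with a count in replicate 1 (horizontal) and replicate 2 (vertical), both on log axes, with equal values on the line and 4 gene lists coloured. Gapdh (956 and 21738 TPM) and many ribosomal protein genes lie above the line, and most mitochondrially encoded genes lie below it.

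An exact binomial test of the reads of these 2 libraries, which compares the libraries and not conditions, placed 8550 of 10635 genes (80.4%) beyond counting noise. Of these, 3961 (46.3%) were higher in replicate 1 and 4589 higher in replicate 2. The split depended on the scaling: with total counts 55.2% were higher in replicate 1, since the median log2 ratio of all genes moved from -0.06 to 0.11. Differences of at least 2-fold were found for 2804 genes, 762 higher in replicate 1 and 2042 higher in replicate 2. Abundant genes were not closer than rare ones on the scale of TPM + 1, which understates differences at low levels. At least 2-fold differences on that scale were found in 22.1% of genes between 1 and 10 TPM, 31.6% between 10 and 100 TPM, 29.6% between 100 and 1000 TPM and 38.1% above 1000 TPM.

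The medians of 5 lists differed between the libraries by more than those of random lists matched on expression, with members going both ways in each. The 20 ribosomal protein genes had a median log2 ratio, replicate 1 over replicate 2, of -1.47, below all 10000 matched lists, with 12 lower and 8 higher in replicate 1. Rplp1 was lower, Rps19 was nearly equal (log2 ratio 0.07) and Rpl5 was 1.57-fold higher, so the list did not move as a unit. The 10 tested genes of hypoxia and glycolysis had a median of -0.98 (0.44 percentile), with 6 lower, among them Aldoa (3.60-fold) and Ldha (3.06-fold), and 4 higher. In the G1/S list the median was -0.51 (2.13 percentile), with 9 of 16 lower, led by the ribonucleotide reductase gene Rrm2 (7.37-fold), and 5 higher. On the scale of TPM + 1, on which genes of every level had a median ratio between 0.21 and 0.41, the G1/S median was 0.04 (7.77 percentile), still low but inside the range of matched lists.

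Higher in replicate 1 were 10 of 13 mitochondrially encoded genes, with 2 lower (median log2 ratio 0.71, 99.9 percentile), among them mt-Nd1 (1.93-fold) and mt-Cytb (1.82-fold). After correction for GC content and transcript length this list (0.43, 96.3 percentile) and the G1/S list (2.63 percentile) no longer stood apart. Histones and RNAs without a poly(A) tail had a median of 0.81 (99.98 percentile), with 11 of 14 higher, among them Rmrp (1.88-fold) and Rpph1 (1.75-fold), and 3 lower, with Rn7sk 9.52-fold higher in replicate 2. With DESeq2 size factors and total counts the medians of these 5 lists had the same directions. Such scalings shift all ratios nearly alike, so that result could hardly differ and adds no test. The counts of members in these 5 lists were identical when adjusted over the list alone, and the remaining 13 of the 18 lists with at least 5 tested members lay inside the central 95% of matched lists before that correction.

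**Figure D4:**
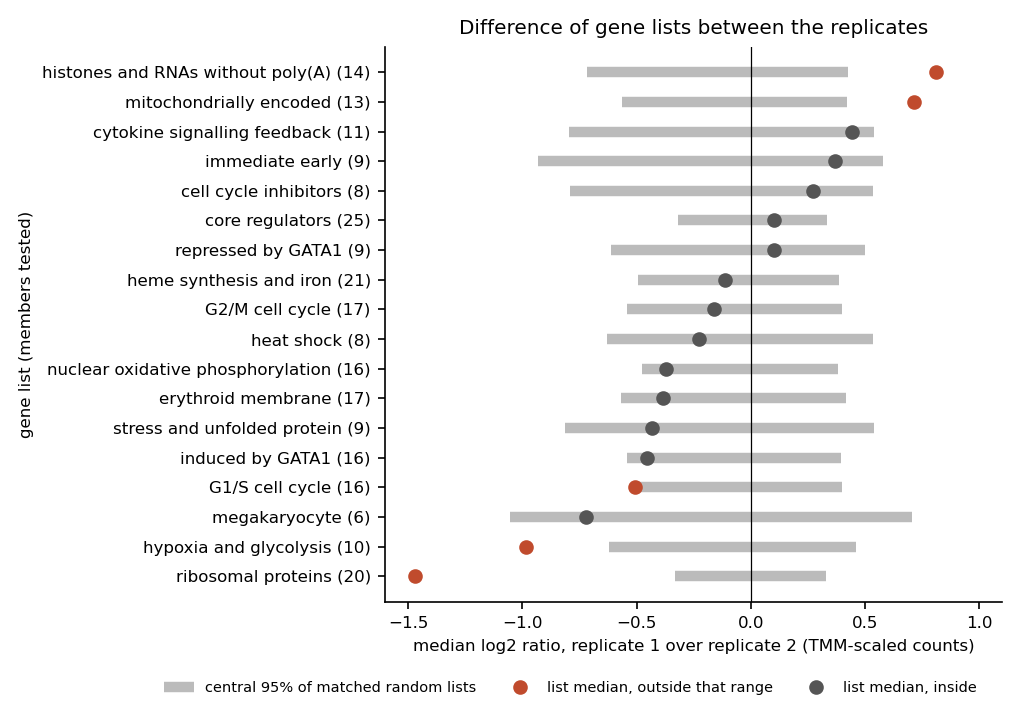
Median log2 ratio of scaled counts, replicate 1 over replicate 2, for 18 gene lists with the number of tested members in brackets, and the central 95% of 10000 random lists matched on expression as grey bars. Ribosomal proteins (-1.47), hypoxia and glycolysis (-0.98) and, at the edge, G1/S genes (-0.51) lie to the left of their bars, and mitochondrially encoded genes (0.71) and RNAs without a poly(A) tail (0.81) to the right; on the scale of TPM + 1, not drawn, the G1/S median was 0.04 (7.77 percentile).

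The largest single differences fell mostly on pseudogenes, whose counts are uncertain because they share reads with their parent genes. Gm10335, a processed pseudogene (chromosome 10, 14523078 to 14523545), had no count in replicate 1 and 87688 in replicate 2. Gm11518, Gm10231, Pagr1b, Gm4294, Rsc1a1, Gm12070 and 1 gene without a symbol (ENSMUSG00000103627.1) also had no count in replicate 1 and between 252 and 3200 counts in replicate 2, and Gm9770 and Rpl27-ps3 were 125-fold and 106-fold higher there. In the other direction, Hist1h4m (378 counts), Gm20695, Rps12l1 and Gm15710 had no count in replicate 2, the mitochondrial gene mt-Co3 (positions 8607 to 9390 of the mitochondrial genome) had 5272 counts in replicate 1 and 71.8 in replicate 2, and Gm7666, Gm2810, Gm12751, Gm10260 and Gm6161 were 63.2-fold to 32.7-fold higher in replicate 1. These sizes depend on how shared reads are divided and, for genes at 0, on the prior count. In the posterior mean counts the log2 ratio, replicate 1 over replicate 2, was 1.51 instead of 6.87 for mt-Co3, 4.04 instead of 7.97 for Hist1h4m, 2.22 instead of 6.79 for Gm15710, -3.34 instead of -8.23 for Gm4294, -2.41 instead of -6.68 for Gm12070, -8.55 instead of -15.10 for Gm10335 and -4.68 instead of -7.55 for the gene without a symbol. The directions of all 20 were the same there. With the counts of all genes sharing sequence summed, the ratio was negative for Rps12l1 (-4.41), Gm7666 (-1.32), Gm10260 (-2.41), Gm2810 (-0.27), Gm12751 (-0.16) and Gm6161 (-0.07).

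Transcript usage was also compared between the libraries. Of 6639 genes with at least 2 annotated transcripts, 4829 (72.7%, exact 95% interval 71.7% to 73.8%) had the same most abundant transcript in both. Among core regulators this held for 20 of 22 genes, and in 10 the leading transcript took at least 90% in both libraries. The leading transcript of Gata1 (ENSMUST00000033502.9) held 99.92% of the TPM of its gene in replicate 1 and 99.99% in replicate 2, and that of Zfpm1 (ENSMUST00000054052.10) held 99.7% and 97.2%. The leading transcript of Gata2 (ENSMUST00000015197.7) held 63.1% and 84.5%, and that of Tal1 (ENSMUST00000162489.1) held 91.3% and 52.7%. The exceptions were Lmo2 and Myc. For Lmo2, ENSMUST00000138815.1 led in replicate 1 with 61.9% and ENSMUST00000156813.3 in replicate 2 with 52.1%. For Myc, ENSMUST00000159327.1 led in replicate 1 with 71.2% and ENSMUST00000191178.1 in replicate 2 with 62.3%.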

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

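Chosen only after the data were seen were total counts as a scaling for the gene lists, random lists matched on GC content, ratios corrected for GC content and length, members sharing sequence with at most 1 other gene, and posterior mean levels of core regulators. No paired analysis was possible because the series holds 1 group. Neither the limit of 2 libraries nor their depth is lifted by any setting, and genes with few counts cannot be ranked between them.

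The number of genes detected ran from 6427 to 10181 over the other levels and units and from 9105 to 9216 with a replicate left out. Pearson's r was 0.868 with a pseudocount of 0.1 and 0.952 with no filter on low values, where genes near 0 enter. Counts beyond counting noise ran from 7969 to 8698, except that requiring at least 2-fold left 2804. The coefficient of variation was 0.524 with no filter on low counts, where low genes enter. A lead of at least 20 percentage points raised the share of genes with the same leading transcript to 75.6%, over fewer genes.

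The 8 lineage contrasts kept their direction under every setting tried. Leaving out members under 0.1 TPM, which leaves fewer genes, lowered the contrast of the erythroid membrane to 0.94 (7 megakaryocyte genes), 1.98 (4 mast cell and basophil genes), 2.76 (2 lymphocyte genes) and 2.27 (3 stem and progenitor genes), no longer past the threshold. The pluripotency and fibroblast contrasts could not be computed there. Lists at or above the 95th percentile numbered 12 to 15 over the settings. Among protein-coding lists matched on GC content the stress and unfolded protein response list fell to the 94.2 percentile, the erythroid membrane to 49.7, immediate early genes to 27.5 and cytokine feedback to 63.4. Without replicate 1 the feedback list lay at 73.8 and without replicate 2 at 96.2.

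The number of lists that differed between the replicates was 5, or 4 with members sharing sequence with at most 1 other gene, where the hypoxia and glycolysis list had too few members left to be tested. With DESeq2 size factors or total counts that number could hardly change, since such scalings shift all ratios nearly alike. The single differences with the largest ratios shrank in posterior mean counts for several genes, among them Gm10335 (-15.10 to -8.55) and mt-Co3 (6.87 to 1.51), with their directions the same. With the ratio of TPM + 1, on which genes of every level had a median between 0.21 and 0.41, the G1/S median was 0.038. That offset of all genes accounts for much of its change of sign, and its place stayed low (7.77 percentile) but inside the range. Cytokine feedback (0.85, 98.8 percentile) came to lie outside the range there. With GC and length correction the mitochondrially encoded list (median 0.43, 96.3 percentile) and the G1/S list (2.63 percentile) came inside the range, the hypoxia and glycolysis list moved to -0.55 (2.03 percentile), and genes induced by GATA1 (-0.49, 2.01 percentile) and cytokine feedback (0.82, 99.9 percentile) came to lie outside it. In expected counts, which carry transcript length, the mean log2 ratios reversed for Gata1 over Gata2 (-0.51), Alas2 over Alas1 (-0.54), Epor over Kit (-0.73) and Nfe2 over Bach1 (-0.10). With a replicate left out Gata1 over Gata2 ran from -0.97 to 1.56. The number of pairs whose first member was higher in both libraries was 6 in expected counts. In a single library the first member was higher in 10 pairs in replicate 2 and in 9 in replicate 1.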

Other observations

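Every test below was chosen only after the result was seen, except the correlation of the ratio with the number of genes sharing sequence. No biological explanation was tested, because the design holds 1 group.

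The medians of the ribosomal protein and the glycolysis lists were lower in replicate 1, although 8 of 20 and 4 of 10 members were higher there beyond counting noise. Over all 30 members the median log2 ratio was -1.40, and 16 members were at least 2-fold lower. After correction for GC content and transcript length the median was -1.11, at the 0.0 percentile of matched lists (ribosomal proteins -1.19, 0.0 percentile, and glycolysis -0.55, 2.03 percentile), and after correction for exons per kilobase it was -1.26, which argues against either trend as the whole cause. With the counts of all genes sharing sequence summed it was -1.68, which argues against reads counted under a copy. The ratio and the number of genes sharing sequence had a Spearman rho of 0.0619 (permutation p = 0.743). A rho at or above 0 had been set before the result as the outcome against shared reads, and it was met. Only after the result was seen was this value judged too close to 0 over 30 genes to decide whether shared reads contribute. Reads discarded before counting, library preparation and culture also stay open.

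Members differed within that pattern. The 8 members sharing sequence with at most 1 other gene had a median of -0.38 (11.2 percentile), inside the matched range, against -1.75 (0.0 percentile) for the 15 sharing with 2 to 9 genes and -1.19 (0.3 percentile) for the 7 sharing with 10 or more. Of those 8, the 5 ribosomal protein genes had a median of -2.01 (0.12 percentile), and the 3 others, Pdk1 (0.45), Vegfa (0.22) and Slc2a1 (-0.35), chosen after their values were seen, were closer to 0. Rps3 (-4.00), chosen after its values were seen, shares sequence with 0 other genes, and Gapdh stood at -4.04 with 88 genes summed. In all, 11 properties of 5695 genes were examined after the list medians were seen. Of those ranked against the ratio, exons per kilobase (-0.15) and mean exon length (0.15) had the strongest correlations. Mean exon length is the inverse of exons per kilobase, so these 2 values are the same result with opposite sign. Chromosome and strand were compared by median log2 ratio instead. The highest and lowest nuclear chromosomes differed by 0.62 and the strands by -0.006. Whether the spread between chromosomes exceeds that of random groups of genes was not tested.

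The largest single differences between the libraries may come from reads shared between genes. Of the 20 genes with the largest differences, 17 share sequence with another gene, against a median of 4 and an upper limit of 8 for the central 95% of matched random lists, and 13 are pseudogenes. Summing the counts of genes sharing sequence decides nothing here, since it shrinks ratios chosen for their size whatever the cause. No counts of another gene could be added for Pagr1b, Gm20695 and Rsc1a1 share sequence with no searched gene, and the gene without a symbol was not searched. That search left out overlapping genes. All 20 genes, these included, had counts that are not whole, as arises where fragments are divided, so shared reads stay possible for them too.

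The labels give the sex of the line as male, yet the listed Y genes, among them Zfy1, Zfy2 and Kdm5d, had no count in either library. Xist, which is in the same list of 8 genes, also had no count, which is not at odds with a male label. A chromosome Y missing from the reference used for counting is argued against by the 1569 genes of that chromosome among those counted. Only 1 of them, the pseudogene Gapdh-ps15, held any count (18.2 expected counts in the 2 libraries). Gapdh shares sequence with 94 genes, so whether those reads come from chromosome Y cannot be told. Low depth is argued against by the X-linked partners of 6 Y genes, chosen after their values were seen: 3 counts would be at most 0.831% of the partner's count in replicate 2, for Zfy1 and Zfx. Whether the cells lost chromosome Y or the label is wrong stays open.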
